A study of Homo sapiens with 4 samples.

How the data were processed

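Chromatin from transformed BJ fibroblasts was immunoprecipitated with 1 monoclonal antibody against TRF1, 1 monoclonal antibody against TRF2 and 1 polyclonal antibody against TRF2, and a further precipitation on protein G beads without antibody served as background. Per the labels' protocols, each precipitation used 175 µg of formaldehyde-crosslinked, sonicated chromatin, antibody precipitations used 25 µg of antibody, and SOLiD fragment libraries were size selected at 150 to 200 nucleotides. Samples were grouped by the antibody named in the labels, which gives 1 library per group.

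Binding sites were called by the authors for each antibody library separately with SISSRs version 1.4 at 2 p-value thresholds, per the file headers. The list at 0.001 is called strict here and the list at 0.05 lenient. Per the file headers, the caller kept 1 tag per genomic position, used a window of 20 bp and a fragment length of 150 bp, and required at least 8 tags per site with at least 2 tags on each side. The same headers give an E-value of 10, a genome length of 3080000000 bp with a mappable fraction of 0.8, and a minimum fold over control of 3 in the strict and 1 in the lenient lists. Every strict peak also stood in the lenient list of the same antibody with the same coordinates. Coordinates are those of hg18, per the submitters' processing notes, and are printed as deposited. The aligner and the treatment of tags that match several places are not given in the sources used here, and such tags weigh most in duplicated sequence near chromosome ends and in satellite arrays.

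Tag count, fold and p-value accompany each peak in the deposited lists. The tag count is a whole-number count of tags, not normalised, per the file headers. The fold is the authors' ratio of these tags to control tags, and the p-value of each peak is the caller's, per the file headers. Fold and p-value belong to a single peak of a single library and were used to describe, rank or filter peaks. The control used by the caller was the same library of 5782703 tags for all 6 lists. The file headers name it IgG, whereas the labels describe beads without antibody, and the labels' description is used here. No peak list of the beads-only library was analysed here.

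Tags per library before the removal of duplicate positions were 6254807 for TRF1, 5591438 for TRF2 monoclonal and 6013380 for TRF2 polyclonal. With a minimum of 8 tags per site, counting error alone is wide: the exact Poisson 95% interval of 8 tags runs from 3.45 to 15.8. Intervals of tag counts are exact Poisson and intervals of shares are Clopper-Pearson at 95%. All of these cover counting error only. Because each antibody has 1 library, each test below compares these peak lists, not conditions, and neighbouring peaks are not independent replicates.

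Peaks of different lists were called overlapping when they shared at least 1 bp. Overlaps were tested against 10000 circular rotations of the other list within each chromosome, over the span of all deposited peaks of that chromosome, one-sided; the smallest p these can give is 0.0001. Strict peaks of the 3 lists were merged where they overlapped, and the merged regions were sorted by the antibodies they held. The preference of TRF2 peaks for the same or the other protein was tested with an exact McNemar test. Recovery of strict and of lenient-only peaks by another antibody was compared with Fisher's exact test in 6 ordered pairs. Folds of shared and single peaks were compared by a two-sided permutation test of the difference in medians with 100000 resamples, whose smallest p is 1e-05. Fold ranks at regions held by 2 antibodies were compared by Spearman's rho with the same number of permutations. Clustering within 10 kb was tested against 10000 uniform placements, and region counts per chromosome by 10000 multinomial draws and by binomial tests in proportion to the span of deposited peaks. Chromosome 13, which held 1 lenient peak each for TRF1 and TRF2 monoclonal and no strict peak, was left out of the chromosome counts. Benjamini-Hochberg adjustment was applied within each family of tests.

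As all lists share a control, unchanged libraries were also simulated against 1 control. Each of the 1529 merged lenient regions received a background estimated from its own ChIP and control tags, Poisson tags were drawn for 3 libraries and 1 control in 1000 runs, and sites were called at 8 tags and a fold of 3. Control tags behind each fold were recovered as tags divided by the fold and by the ratio of library sizes. At sites of 40 bp these came out whole in 69 of 69 strict TRF1 sites, 75 of 75 TRF2 monoclonal sites and 75 of 75 TRF2 polyclonal sites, within 0.02 tags or the rounding of the fold where that is wider. At lenient-only sites of 40 bp they were compared between sites found and not found again by another antibody, with labels permuted 100000 times among sites of equal tag count. Between 40.6% and 42.7% of the strict sites of 40 bp had 1 control tag or fewer, so their fold reflects the tag count almost alone.

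Regions named in the text followed a rule fixed in advance. It takes the 10 shared regions with the best mean fold rank, the 3 highest single-antibody peaks per antibody that meet no lenient peak of another antibody, the 3 clusters with the most strict peaks per antibody, and every strict peak around the ancestral fusion site on the long arm of chromosome 2. That last part was searched from 108 to 119 Mb. Designs, alternatives and this rule were set before the data were examined. Splits by dense or sparse surroundings, shifts of 10 to 100 kb, runs without chromosome M, tag count in place of fold, polyclonal peaks in the McNemar test, chained regions near chromosome starts, positions of outermost peaks and the control tag tests were chosen after seeing the data. Dense surroundings means 5 or more other lenient regions within 100 kb.

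No genome sequence of hg18 was used here, so nearest genes, distance to centromeres and to the far chromosome ends, and repeat content of the regions were not computed. Overlap, 3-way and median tests were tested on simulated data before use. In 100 simulated pairs of independent lists modelled on TRF1 and TRF2 monoclonal, 1 pair was called, and with 10 planted shared sites 100 of 100 were recovered. For regions of 3 antibodies, 0 of 100 independent sets were called and 100 of 100 planted sets were recovered. In these simulated lists each peak was placed independently and chromosome M was left out. Planted sites were exact copies of peaks of the first list, so their recovery was close to certain. The simulated lists do not show how well partial overlaps are found or how often clustered lists would be called. For TRF1 folds split at random 5 of 100 splits were called, and 100 of 100 were called when the folds of 1 class were multiplied by 2. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.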

Results

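TRF1 and TRF2 are shelterin proteins that bind the TTAGGG repeats of telomeres. Their binding across the genome was profiled by ChIP-seq in BJ fibroblasts, a human foreskin fibroblast line that was transformed with SV40 large T antigen, telomerase and oncogenic H-Ras. Libraries were made with a TRF1 monoclonal antibody, a TRF2 monoclonal antibody and a TRF2 polyclonal antibody, 1 library each, beside a control of beads without antibody. The caller used 5114540 tags for TRF1, 4807597 for TRF2 monoclonal and 5137085 for TRF2 polyclonal after removal of duplicate positions, against a control of 5782703 tags. There were no replicates, so differences between antibodies have no replicate error, and tests below compare these peak lists only. The study asked whether both proteins bind telomere-like repeats and satellite repeats within chromosomes, and coordinates are given in hg18.

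At the strict threshold 139 peaks were called for TRF1, 133 for TRF2 monoclonal and 133 for TRF2 polyclonal. They covered 13820, 10820 and 12720 bp. Many peaks of each antibody lay in short runs rather than alone, and 1 of 3 runs of 6 strict TRF1 peaks was at the highest coordinates of chromosome 3 with a deposited peak, 199384271-199385751, with 166 tags. The same place held 5 TRF2 monoclonal peaks with 156 tags and 5 TRF2 polyclonal peaks with 142 tags. Median tags per strict peak were 11, 12 and 13 in that order, and the authors' median folds over control were 7.46, 6.62 and 6.19. The lenient lists held 953, 992 and 976 peaks, with median folds of 1.41, 1.39 and 1.39.

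The first question was whether TRF1 and TRF2 were found at the same sites. Of 139 strict TRF1 peaks, 69 overlapped a TRF2 monoclonal peak (49.6%, 95% interval 41.1 to 58.2) and 69 overlapped a TRF2 polyclonal peak. Within this run on chromosome 3 the site at 199385711-199385771 had the highest mean fold rank of those shared by all antibodies, with 45 tags for TRF1 (fold 50.9), 52 for TRF2 monoclonal (62.6) and 48 for TRF2 polyclonal (54.0). The last deposited peak site of chromosome 20, 62388571-62389271, had best folds of 62.2, 42.1 and 37.2, and 114, 131 and 84 tags over all of its peaks. In 10000 rotations the overlap of TRF1 with TRF2 monoclonal averaged 0.0225 peaks and that with TRF2 polyclonal 0.0963, and p was 0.0001 for both, the smallest the rotations can give (one-sided). All lists share 1 control, and simulated libraries without enrichment shared 4.87 and 5.29 regions on average, with at most 15 and 14 in 1000 runs, so part of each overlap may come from the control.

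Both TRF2 antibodies met at 69 of 133 TRF2 monoclonal peaks (51.9%, 95% interval 43.1 to 60.6). Rotations gave 0.107 on average (permutation p = 0.0001, the smallest possible), and the simulation with a shared control gave 4.88. TRF2 monoclonal peaks overlapped the TRF1 list at 72 sites and the TRF2 polyclonal list at 69. Among the 17 peaks found by only 1 of these lists, 7 were in the TRF2 polyclonal list and 10 in the TRF1 list (41.2% same protein, 95% interval 18.4 to 67.1; exact McNemar p = 0.629, two-sided). A difference between same-protein and other-protein overlap was thus not detectable with 17 peaks. When peaks within 1 kb counted as shared the split was 5 against 15 (exact McNemar p = 0.0414), and in the lenient lists it was 155 against 144 (p = 0.563), the opposite direction.

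Merging the strict lists gave 251 regions, of which 59 held a peak of all 3 antibodies. Shared regions included the first bases of several chromosomes in the assembly, where chromosome sequence adjoins the telomere. On chromosome 9 the region 11-411 had best peaks of 50 tags for TRF1, 34 for TRF2 monoclonal and 44 for TRF2 polyclonal, with folds of 53.1, 39.7 and 49.5. On chromosome 1 the region 71-471 had 125, 118 and 131 tags over all of its peaks, the last in 2 TRF2 polyclonal peaks. Chromosome 18 had 3 named regions in its first 100 kb, at 331-451, 591-751 and 95231-95331, with folds from 16.8 to 38.5 over the 3 antibodies. The region at 531-711 on chromosome 2 had 32, 18 and 21 tags, and the last deposited site of chromosome 10, at 135374011-135374711, had 77, 83 and 111 over all of its peaks. Rotation of 2 lists gave 0.0039 regions on average and never more than 1 (permutation p = 0.0001, the smallest possible), and the shared-control simulation gave 2.12 on average and at most 9. Another 61 regions held TRF1 alone, 54 TRF2 monoclonal alone and 52 TRF2 polyclonal alone. TRF1 paired with TRF2 monoclonal in 9 and with TRF2 polyclonal in 9, and the TRF2 antibodies paired without TRF1 in 7.

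**Figure D1:**
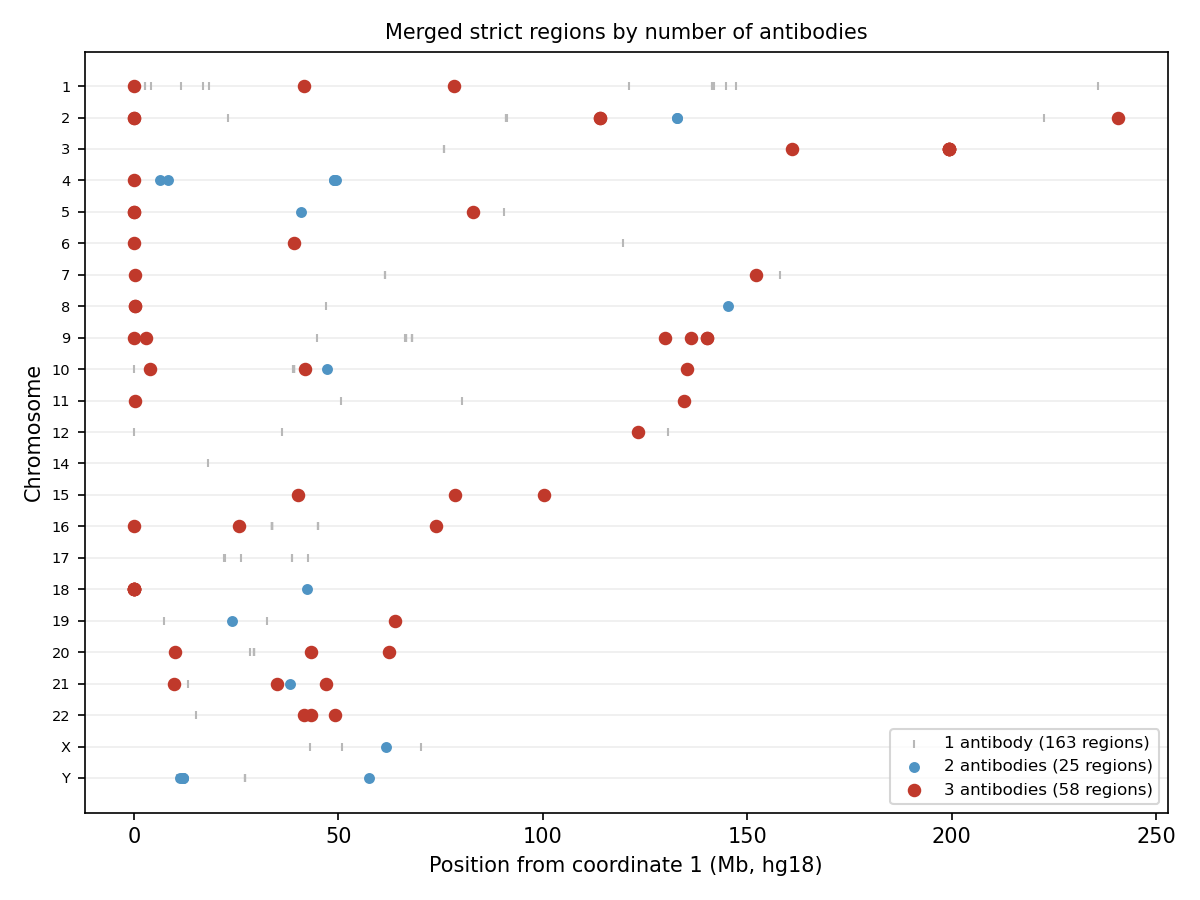
Positions of the 246 merged strict regions on nuclear chromosomes (x axis, Mb from coordinate 1 in hg18; y axis, chromosome). Grey ticks are the 163 regions of 1 antibody, blue points the 25 of 2 and red points the 58 of 3; 19 of the red points lie in the first 500 kb of a chromosome.

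Position along the chromosome differed between shared and single-antibody regions. In the first 500 kb of a chromosome lay 30 of 246 nuclear regions (12.2%, 95% interval 8.38 to 16.9), where uniform placement gave 1.38 (one-sided permutation p = 0.0001, the smallest possible). Regions of all 3 antibodies accounted for 19 of these, spread over 11 chromosomes. This was 32.8% of the 58 nuclear shared regions, against 9 of 163 single-antibody regions or 5.52% (Fisher exact p = 7.88e-07). The single-antibody share was itself above the 0.559% that uniform placement gave for all nuclear regions, a difference not tested for that class alone. Other shared regions lay well inside chromosomes, among them 160894691-160894751 on chromosome 3, with 19, 19 and 20 tags and folds of 21.5, 22.9 and 22.5. Neighbouring regions of one chromosome start are not independent, and with regions within 10 kb chained the counts were 14 of all 3 antibodies against 3 of 1 (odds ratio 11.5, Fisher exact p = 3.43e-05).

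The fusion site on the long arm of chromosome 2, a relic of the ancestral joining of a pair of chromosome ends that left telomeric repeats inside the chromosome, held strict peaks in all 3 libraries. Strict peaks there spanned 680 bp, 114076811-114077491, with 50 tags in 3 TRF1 peaks, 24 tags in 2 TRF2 monoclonal peaks and 34 tags in 3 TRF2 polyclonal peaks. At 114077451-114077491 the peaks of the 3 antibodies had the same coordinates, with 23 tags (95% interval 14.6 to 34.5) and a fold of 26.0 for TRF1, 12 tags (6.20 to 21.0) and 14.4 for TRF2 monoclonal, and 9 tags (4.12 to 17.1) and 10.1 for TRF2 polyclonal. A TRF1 peak at 114076811-114076851 (11 tags) and a TRF2 polyclonal peak at 114076891-114077011 (16 tags) overlapped no peak of another antibody, although each was inside this span. One further TRF2 monoclonal peak lay at 114098591-114098651 with 8 tags.

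**Figure D2:**
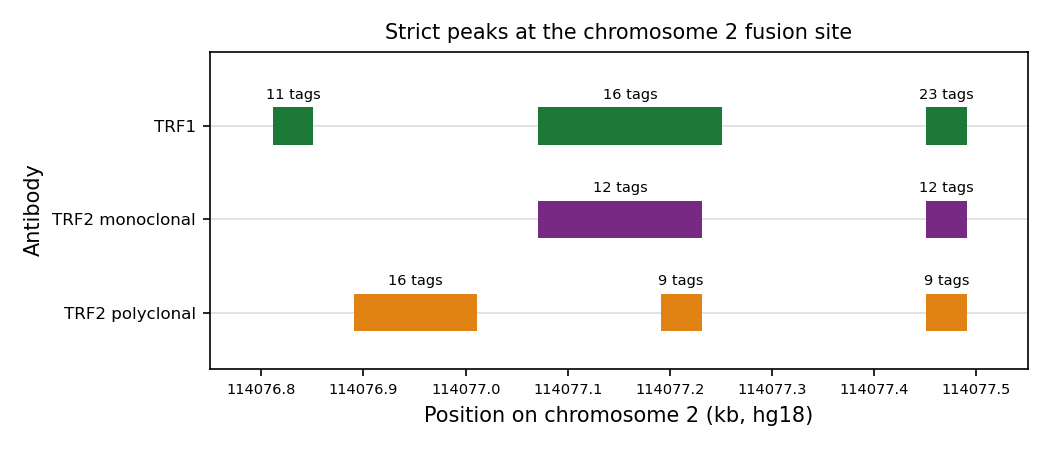
Strict peaks of each antibody (y axis) at the chromosome 2 fusion site (x axis, position in kb, hg18). Each bar is a called peak labelled with its tag count; the rightmost peak has the same coordinates in all 3 libraries, with 23 tags for TRF1, 12 for TRF2 monoclonal and 9 for TRF2 polyclonal.

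Sites found with a single antibody had lower folds. Leading TRF1 peaks with no lenient peak of another antibody were at 44819491-44819531 on chromosome 9 (13 tags, fold 14.7), the fusion-site peak above, and 75781031-75781151 on chromosome 3 (10 tags, 11.3). For TRF2 monoclonal they were at 80275571-80275611 on chromosome 11 (11 tags, 13.2), 11422771-11422811 on chromosome 1 (10 tags, 12.03) and 9809551-9809611 on chromosome 21 (10 tags, 12.03). TRF2 polyclonal had the fusion-site peak above, then 100231-100271 on chromosome 10 (10 tags, 11.3) and 109551-109591 on chromosome 7 (9 tags, 10.1). Median fold of strict peaks shared with another antibody was 11.3 against 4.52 in the rest for TRF1 (78 and 61 peaks, permutation test, adjusted p = 1.5e-05). It was 10.8 against 4.61 for TRF2 monoclonal (79 and 54 peaks, permutation test, adjusted p = 5e-05) and 10.1 against 3.69 for TRF2 polyclonal (81 and 52 peaks, adjusted p = 1.5e-05). Sharing and fold are not separate here, since every strict list has the same minimum fold of 3 over the same control. A peak near that cut can miss it in another list by counting error alone, so part of this difference is set by the cut. In the lenient lists the difference had the opposite sign for each antibody (-0.42, -0.23 and -0.16, adjusted p from 3e-05 to 0.00209). When sharing with a lenient list counted, the differences for both TRF2 antibodies no longer passed the test (3.34 and 3.57, permutation tests, adjusted p = 0.0864 for both), nor did that for TRF2 polyclonal in sparse surroundings (1.12, adjusted p = 0.691).

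**Figure D3:**
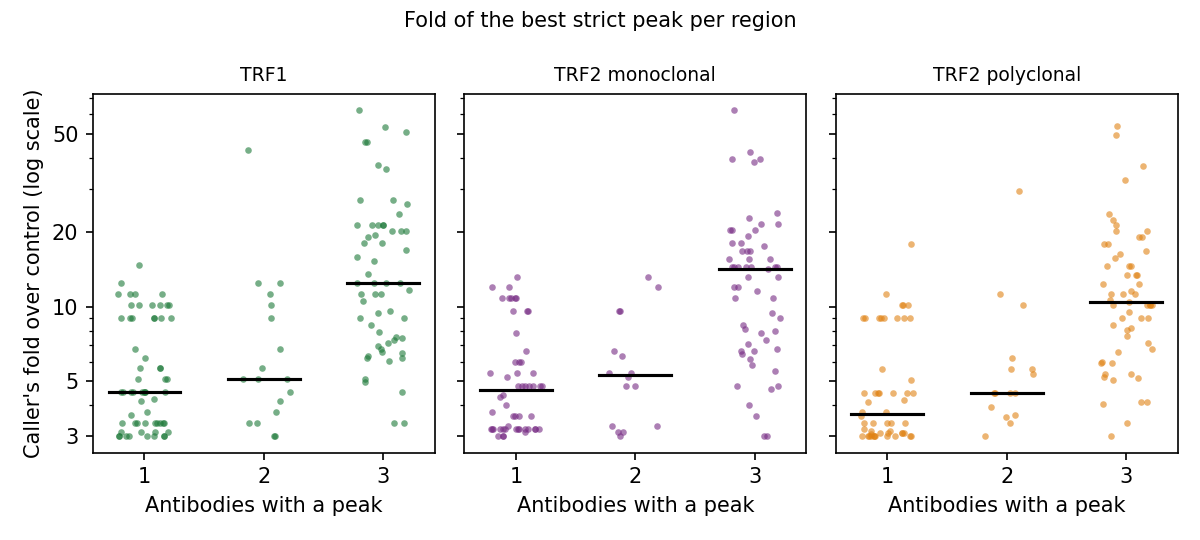
Fold over control of the best strict peak per region (y axis, log scale) by the number of antibodies with a peak there (x axis), 1 panel per antibody. Points are regions and black lines medians, which are 12.4 for TRF1, 14.2 for TRF2 monoclonal and 10.5 for TRF2 polyclonal in regions of 3 antibodies and 4.52, 4.61 and 3.69 in regions of 1.

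Regions that were strong with one antibody were strong with the others. Across the 69 regions shared by TRF1 and TRF2 monoclonal, folds had a Spearman rho of 0.920, across 68 regions of TRF1 and TRF2 polyclonal 0.842, and across 68 regions of the TRF2 antibodies 0.916 (permutation p = 1e-05 each, the smallest possible, adjusted p = 1e-05 over 3 pairs). In the lenient lists, with 554 to 570 regions per pair, rho was 0.599, 0.635 and 0.619 (permutation p = 1e-05 each). These correlations are across regions, which are not independent replicates. Tag counts, which do not contain the control, gave 0.891, 0.852 and 0.875. The covariance of log2 folds was 0.93, 0.87 and 0.93, against 0.15, 0.16 and 0.14 in the simulation with a shared control and no enrichment. Pearson's r of log2 folds was 0.92, 0.83 and 0.92, and the same simulation gave 0.73, 0.74 and 0.72. The simulated r thus belongs to a covariance well below the observed one. Simulated backgrounds had a median of 11.8 control tags, whereas strict sites of 40 bp had a median of 2.00 with each antibody. The simulation therefore cannot give the share of the observed covariance or r that comes from the shared control. No simulated value was computed for the lenient lists or for tag counts, so their rho is set against 0 only.

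Recovery by another antibody was compared between strict peaks and peaks of the lenient list alone. TRF2 polyclonal strict peaks were found in the lenient TRF1 list in 69.2% of 133 cases, against 58.2% of 843 lenient-only peaks, the widest gap of 6 ordered pairs (Fisher exact, adjusted p = 0.105). Strict TRF1 peaks were recovered in 57.6% and 55.4% of cases by TRF2 monoclonal and polyclonal, against 60.8% and 61.5% of lenient-only peaks. None of the 6 differences passed the adjusted threshold at an overlap of 1 bp. Within 1 kb strict TRF1 peaks had the lower recovery by TRF2 monoclonal (74.8% against 84.8%, Fisher exact, adjusted p = 0.0191) and by TRF2 polyclonal (72.7% against 85.01%, adjusted p = 0.00482). With peaks chained within 10 kb, strict clusters of TRF2 monoclonal and TRF2 polyclonal had the higher recovery by TRF1 (84.2% against 69.5% and 89.4% against 67.1%, Fisher exact, adjusted p = 0.0397 and 0.000709). Against the other antibody's strict list 49.6% to 54.9% of strict peaks were recovered and 0.949% to 2.70% of lenient-only peaks, a gap largely set by definition, since lenient-only peaks failed the strict cut over the same control. Among peaks in sparse surroundings strict peaks had the higher recovery in all 6 pairs. The difference passed the adjusted threshold in the 4 pairs that started from a TRF2 antibody, with 17.4 to 26.2 percentage points (Fisher exact tests, adjusted p from 0.00440 to 0.0403), and not in those of TRF1, with 6.97 and 8.08 (adjusted p = 0.429 and 0.413). In dense surroundings strict peaks had the lower recovery in all 6 pairs, by 1.90 to 17.1 percentage points, and none of these differences passed (Fisher exact tests, adjusted p from 0.0585 to 0.799).

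Runs of neighbouring peaks were frequent with each antibody. A neighbour of the same strict list started within 10 kb of 41.7% of TRF1 peaks (95% interval 33.4 to 50.4), 41.4% of TRF2 monoclonal peaks (32.9 to 50.2) and 50.4% of TRF2 polyclonal peaks (41.6 to 59.2). Uniform placement gave 0.249%, 0.164% and 4.64% (permutation p = 0.0001, the smallest possible). Within 1 kb the shares were 17.3%, 20.3% and 28.6%, and in the lenient lists, within 10 kb, they were 84.7%, 85.99% and 86.5% (permutation p = 0.0001 for each). Each antibody had 8 clusters of at least 3 peaks. Beside the run on chromosome 3, those with most peaks were on chromosome Y for TRF1 at 11932491-11945031 (6 peaks, 58 tags) and 57388031-57406131 (6 peaks, 82 tags). For TRF2 monoclonal they were at 57383991-57400651 on chromosome Y (5 peaks, 51 tags) and 48807111-48816291 on chromosome 4 (4 peaks, 43 tags). For TRF2 polyclonal they were the mitochondrial genome, with 6 peaks and 345 tags between 31 and 16511, and 135372471-135374711 on chromosome 10 (5 peaks, 130 tags). The highest folds in the TRF1 runs on chromosome Y were 5.09 and 4.52, and that in the run on chromosome 4 was 10.8.

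Some chromosomes held more strict regions than their span gives (exact multinomial test by random draws, p = 0.0001, the smallest possible). Span is that of all deposited peaks, in strict and lenient counts alike, as chromosome lengths were not used. A chromosome whose peaks cover only part of its length thus gets too low an expected number. On chromosome 4 the last lenient peak was at 80493591, so its excess below may come from the span used. Chromosome Y had 34 regions where 4.66 were expected, 7.29 times as many (exact binomial test, adjusted p = 8.14e-18), and chromosome 21 had 20 where 3.71 were expected (5.39 times, adjusted p = 1.41e-08). Chromosomes 4 and 16 had 17 and 16 regions where 8.02 and 7.37 were expected (exact binomial tests, adjusted p = 0.0157 for both), and chromosome 6 had 3 where 15.7 were expected (adjusted p = 0.00119). Chromosomes 5, 8, 12 and 14 were also below expectation, with 5, 5, 4 and 1 regions where 13.4, 14.5, 13.01 and 6.90 were expected (exact binomial tests, adjusted p from 0.0189 to 0.0427). The short mitochondrial genome held 5 regions where 0.00164 were expected (exact binomial test, adjusted p = 1.15e-15). That expectation takes span alone and not the number of genome copies per cell. Of these regions 4 held TRF2 polyclonal alone, with folds from 3.20 to 4.50, and 1 held all 3 antibodies. Clusters left 1 on the mitochondrial genome (exact binomial test, adjusted p = 0.0119). Of the 34 regions on chromosome Y, 29 held 1 antibody, 5 held 2 and 0 held 3. With regions chained within 10 kb into clusters, chromosome Y had 9 clusters, 3.19 times the expected number (exact binomial test, adjusted p = 0.0183). Counting only regions of at least 2 antibodies, the ratio for chromosome Y was 3.20 (exact binomial test, adjusted p = 0.122) and that for chromosome 21 was 5.64 (adjusted p = 0.00620). Chromosomes 4, 6 and 16 no longer passed with clusters (exact binomial tests, adjusted p = 0.217, 0.164 and 0.193) or with regions of at least 2 antibodies (0.252, 0.389 and 0.887), nor did chromosomes 5, 8, 12 and 14 (adjusted p at least 0.299 in both). With regions of at least 2 antibodies chromosome 18 passed, with 8 regions where 2.50 were expected (exact binomial test, adjusted p = 0.0291). Most of these lay in its first 100 kb. With clusters chromosome 18 had 4 where 4.53 were expected, and in the lenient lists 36 regions where 45.5 were expected, and neither passed. In the lenient lists chromosomes 4, 6 and 16 passed again in the same direction, with ratios of 2.76, 0.230 and 2.76 (exact binomial tests, adjusted p at most 1.46e-19), and so did chromosomes 5, 8, 12 and 14, with 0.332, 0.466, 0.391 and 0.262 (adjusted p at most 3.22e-08). Chromosome 10 held 236 lenient regions where 82.1 were expected (exact binomial test, adjusted p = 2.58e-46), against 21 strict regions where 13.5 were expected (adjusted p = 0.0907). With clusters it had 11 where 8.16 were expected (exact binomial test, adjusted p = 0.373). Most chromosomes passed in the lenient lists, among them chromosome 9 with a ratio of 0.470, against 1.15 in strict regions. The binomial tests take regions as independent, but 84.7% to 86.5% of lenient peaks had a neighbour of the same list within 10 kb. Small p-values there can thus count the same run of peaks many times. Strict peaks on chromosome Y numbered 22 for TRF1, 11 for TRF2 monoclonal and 6 for TRF2 polyclonal, a difference that did not pass the adjusted threshold over 24 chromosomes (permutation p = 0.0055, adjusted p = 0.132).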

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

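Of 149 alternative values over 26 results, 105 kept their direction and their side of the threshold, 13 crossed it upward, 4 crossed it downward, 16 reversed and 11 were counts that moved by over 1.5 times. Runs with dense or sparse surroundings, without chromosome M, with a shift of 10 to 100 kb, with tag count in place of fold and with chained regions near chromosome starts were chosen after seeing the data. All 4 overlap results (the 3 pairs and the regions of 3 antibodies) kept a permutation p of 0.0001, the smallest possible, in each of their alternatives; the pair overlaps ranged from 47 to 82 peaks in strict lists outside the splits by surroundings and the regions of 3 antibodies from 41 to 59.

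Lenient lists raised the counts by construction, to 953, 992 and 976 peaks, to overlaps of 575, 578 and 600 and to 419 shared regions; dense surroundings left 20, 20, 19 and 15. The same-protein difference of -3 peaks became 11 in lenient lists and -10 within 1 kb. Recovery of strict minus lenient-only peaks, in percentage points, moved most, its values against the strict list largely by definition of the lists. For TRF1 in TRF2 monoclonal (-3.26) it was -9.95 within 1 kb, 48.3 against the strict list and 6.97 in sparse surroundings. For TRF1 in TRF2 polyclonal (-6.15) these were -12.4, 46.9 and 8.08, and 0.523 with peaks chained within 10 kb. For TRF2 monoclonal in TRF1 (3.50) they were -0.467, 52.7 and 19.8, with 14.7 chained and -10.3 in dense surroundings. For TRF2 monoclonal in TRF2 polyclonal (2.22) they were -2.03, 49.7 and 21.6, with -14.9 in dense surroundings. For TRF2 polyclonal in TRF1 (10.9) the strict list gave 53.9, chaining 22.3, sparse surroundings 26.2 and dense surroundings -1.90. For TRF2 polyclonal in TRF2 monoclonal (4.44) the values were -5.08 within 1 kb, 51.7 against the strict list, 17.4 in sparse and -9.93 in dense surroundings. Fold differences between shared and single peaks turned to -0.42, -0.23 and -0.16 in lenient lists, and fell short of the threshold at 3.34 and 3.57 for the TRF2 antibodies when sharing with a lenient list counted and at 1.12 for TRF2 polyclonal in sparse surroundings, where 10 single peaks were left. The ratio for chromosome Y was 3.20 with regions of at least 2 antibodies. Except for the counts, the cause of these changes was not tested beyond the tests given below.

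Depth limits the precision of single sites: 43.9%, 39.1% and 36.8% of strict peaks rest on 10 tags or fewer. Not run, for lack of a genome of this build, were distances to centromeres and far chromosome ends and the telomeric and satellite repeat content with its other windows. No paired analysis was possible because each antibody has 1 library.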

Other observations

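Apart from the recovery shares themselves, the tests in this part were chosen after the data were seen. Shared regions were not confined to the first 500 kb of chromosomes or to the surroundings of their last deposited peaks. Of 58 nuclear regions of 3 antibodies, 19 lay in the first 500 kb of a chromosome, 16 within 500 kb of its last deposited peak and 23 elsewhere, and the median fold elsewhere was 12.8 against 13.7 in the first 500 kb. Some of those elsewhere, chosen after their values were seen, were 25678931-25678971 on chromosome 16 (36, 30 and 29 tags for TRF1, TRF2 monoclonal and TRF2 polyclonal), 3976191-3976231 on chromosome 10 (19, 17 and 14 tags) and 43375391-43375511 on chromosome 20 (19, 10 and 10 tags). Single-antibody regions lay elsewhere in 138 of 163 cases, with a median fold of 4.37 there against 9.62 in the 9 of the first 500 kb. On the side of low coordinates the outermost strict region was of all 3 antibodies on 11 of 23 chromosomes. On the side of high coordinates it was so on 11 of 23 too, where 7.13 were expected for each (one-sided permutation p = 0.0392 and 0.0396). These are outermost called regions, which need not lie near a chromosome end. Those counted at low coordinates included 40030491-40030531 on chromosome 15, where lenient peaks began at 18265671, and 10120171-10120231 on chromosome 20. Of the 167 single-antibody regions, 17 lay within 200 bp and 83 within 10 kb of a strict peak of another antibody.

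Regions of 3 antibodies were weighed against a shared low control and against pile-ups in repeat arrays, and no other artefact was tested. By the labels' description the control had no antibody. Sites that any antibody precipitates without its target would not be removed by such a control, so they stay open. If a chance low count in the control made the regions of 3 antibodies, its count would stay within a Poisson draw at the scaled ChIP level. Of 50 such regions with a 40 bp site, 41 had fewer control tags than that, after Bonferroni adjustment over 1529 lenient regions (median 1 control tag where 19.6 were expected). This argues against a chance draw among those 1529 regions only. Strict sites needed a fold of 3 over this same control, and the lenient regions were called against it too. Low control counts are thus partly set by the calling, and the adjustment does not cover the search over the genome, so the explanation is not excluded for the 41. Another 18 regions stay open as well (9 above that bound and 9 with no 40 bp site to test). Pile-ups in repeat arrays, for which dense surroundings stand in here without an annotation of repeats, would put shared regions in the densest surroundings. Their median number of lenient regions within 100 kb was 0.5 against 14 for single-antibody regions (difference -13.5, permutation p = 0.00373). Shared regions thus lay in sparser surroundings, but this count cannot exclude pile-ups. Overlapping peaks of several lists count as 1 lenient region, which can lower the count near shared regions. Pile-ups at isolated positions have few neighbours and were not tested. Shared regions stay open to this explanation, including the 14 nuclear ones in dense surroundings. Their concentration near chromosome starts (odds ratio 11.5 with chained regions, Fisher exact p = 3.43e-05) is in line with binding of TRF1 and TRF2 near chromosome ends, a hypothesis that leaves the regions elsewhere unexplained. Sequence near chromosome ends is also duplicated between chromosomes, and how tags of several matches were placed was not tested.

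Regions of 1 antibody may in part be counting noise at the caller's minimum of 8 tags. Regions of 3 antibodies had a median of 18 tags and those of 1 antibody a median of 9, a difference of 9 tags (permutation p = 1e-05, the smallest possible), but weak real sites would also have few tags, so this test leaves noise open. If many of the 106 regions of 1 TRF2 antibody were sites of TRF2 without TRF1, the TRF2 antibodies would pair more often than other pairs; they made up 7 of the 25 regions of exactly 2 antibodies, 28% with a 95% interval of 12.1 to 49.4, where equal pairing gives 33.3%. This interval is too wide to decide, so noise, weak binding and TRF2-specific sites cannot be told apart for those 106 regions.

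At an overlap of 1 bp, lenient-only peaks were found again by another antibody in 58.2% to 61.5% of cases and strict peaks in 55.4% to 69.2%, but within 1 kb strict peaks of TRF1 were found again less often and with chaining those of both TRF2 antibodies more often by TRF1. A candidate explanation is positions of high background in every library, the control included. Lenient-only sites of 40 bp that were found again had more implied control tags than the others, but also more tags (medians of 14.5, 14 and 14 against 10 for each antibody), and among sites of equal tag count the mean differences were 0.468, 0.283 and 0.469 control tags (permutation tests, adjusted p = 0.322 for all), so this explanation stays open. A bearing of repeat arrays stays open too: dense surroundings, which stand in for them, hold 88.9% to 90.2% of lenient-only and 44.6% to 51.9% of strict peaks, and strict peaks had the higher recovery in all 6 pairs in sparse surroundings, past the adjusted threshold in 4, and the lower in all 6 in dense surroundings, past it in 0. No biological explanation was tested for this pattern.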
